A study of Arabidopsis thaliana with 8 samples.

How the data were processed

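The series holds 8 libraries of SPARE (Specific Parallel Analysis of RNA Ends), which reads the 5′ ends of the RNA fragments that remain after a MIRNA precursor is cleaved. Per the labels, total RNA of 10-day-old seedlings was ligated with T4 RNA ligase, reverse-transcribed with primers specific to the precursors and amplified in repeated rounds of PCR. Cutadapt and the TAIR10 build are named in the submitters' processing notes, without versions, and the aligner is not given in the sources used here. The deposited files give, for each tag, the raw counts of identical sequences together with the precursor, the start position, the length and an alignment hit column. No normalisation had been applied to these counts by the authors, as judged from whole numbers and from totals that differ between libraries. There were 13 entries with a blank count, 10 of them of miR408 and all in the fiery1 libraries, and these were left out.

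File entries that lay on the same stretch of genome, within 5 nt, were summed, which turned 111 entries into 108 precursors. Each precursor was placed on the TAIR10.1 reference by exact matching of its tags, and 99.57% of the counts matched at the locus so found. Mature miRNA positions came from the annotation of that reference, and the opposite strand of the duplex was predicted with RNAfold 2.7.2 where only the other arm was annotated. The base-proximal end was defined as the position just after the 3′ end of the duplex strand on the 3′ arm. The loop-proximal end was the 5′ end of the same strand. Both were counted within 1 nt, over the 85 precursors with a 3′ arm annotated in the reference (71 of them among tags of 26 nt or more).

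Total counts per library were 80166 and 126556 in wild type, 470789 and 821562 in fiery1, 45653 and 35860 in hyl1, and 299513 and 510438 in se. Tags of 26 nt or more made up 56554 and 121429 of these counts in wild type, 453388 and 795030 in fiery1, 45108 and 25753 in hyl1, and 41677 and 82159 in se. A floor of 3 counts per library stood for a group without counts, and ratios with 1 to 3 counts in a group were given an exact 95% counting interval. A fold given as at least a value is the mean CPM of the other group over the mean floor. A single library can lie below that fold. The reads carry no molecular identifiers, so these intervals and floors cover counting error only. A precursor lost whole from a library could stand above the floor, so a fold given as at least a value is not a strict bound.

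Precursor abundance was tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr with a minimum count of 10) in 1 model of all 8 libraries with a term per genotype. Adjusted p-values are Benjamini-Hochberg values over the precursors tested, with a threshold of 0.05, and the spread they use is that between libraries, which may be technical. Precision was the share of a precursor's counts at its main position, the position with the highest share averaged over the 4 genotypes. The same libraries set that position and were then tested, so a high share in 1 genotype favoured its choice. It was tested with limma 3.58.1 on the logit scale with an offset of 0.5, for precursors with at least 20 counts in each library. Library measures (base-proximal and loop-proximal shares, median precision, and distinct positions at equal depth) were compared with exact two-sided permutation tests. With 2 libraries against 2 there are 6 arrangements and the smallest possible p is 0.33. Positions were counted after 100 seeded draws that thinned each library to 35860 counts, or to 25753 for tags of 26 nt or more.

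The 11 lists of precursors were defined by family number. They were loop-to-base families (MIR156, MIR159, MIR160, MIR162, MIR171, MIR319), sequential loop-to-base families (MIR159, MIR319), and short base-to-loop conserved families (MIR164 to MIR169, MIR172, MIR390, MIR393, MIR395 to MIR399, MIR403, MIR408). Others were conserved development regulators (MIR156, MIR159, MIR160, MIR164 to MIR167, MIR169 to MIR172, MIR319, MIR390, MIR393, MIR394, MIR396), nutrient-responsive families (MIR395, MIR397, MIR398, MIR399, MIR408, MIR827, MIR857), sulfate (MIR395), phosphate (MIR399, MIR827), copper (MIR397, MIR398, MIR408, MIR857), silencing-pathway regulators (MIR162, MIR168, MIR403, MIR838), auxin-receptor and ARF families (MIR160, MIR167, MIR393), and families outside the conserved numbers. Lists were tested with camera (preset correlation 0.01) in limma, with an estimated correlation and with fry as alternatives. Single families with at least 3 tested members (MIR156, MIR166, MIR167, MIR169, MIR172, MIR395, MIR399) were described by count.

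Precursors were named by a rule. For each comparison it took up to 12 of the largest rises and 12 of the largest falls among those with an adjusted p under 0.05 whose libraries did not overlap, and, where fewer than 6 passed, the 6 with the smallest p as values only. In the precision comparisons it took the largest rises and falls in the same way. The most counted members of each list and a fixed set of well-known precursors could also be given. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. The counts on tags of 26 nt or more, also tried at 31 nt and 46 nt, were added after the data were examined, as were the fits that kept file entries apart, that used tags with 0 in the hit column, that left out MIR159b, that predicted the 3′ arm, that crossed the replicate block (the first library of a genotype set with the second of the other), that added a term for the libraries with later sample numbers, that rescaled the lists, or that left out single libraries from the list tests and library measures.

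The alternatives were DESeq2 size factors or library totals in place of TMM, no filter or a stricter filter on low counts (50 in total and 20 in 2 libraries), the DESeq2 1.42.0 Wald test, only the 2 genotypes compared, a replicate block, each precursor's most used position left out, thinning, and each library left out in turn. Precision was repeated with minimum counts of 10 and 50, with 1 nt on each side of the main position, and with an inverse Simpson index. The index was taken as its negative log, so that a higher value means more concentrated ends. The tests were tried on simulated data with known changes. Counts were drawn from a negative binomial with the mean of each precursor over all libraries and its estimated dispersion, and logit shares with normal errors. Loss of whole positions from 1 library of a genotype was not simulated. The rates may therefore not hold for precursors without counts in a group. edgeR recovered 7% to 10% of 8-fold changes and 45% to 52% of 64-fold changes over all tags, and 3% to 6% and 26% to 41% over tags of 26 nt or more. It called at most 0.49% of unchanged precursors. For limma, 48% to 70% of shifts of 4 on the logit scale were recovered and up to 3.08% of unchanged precursors were called. Software was R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.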

Results

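SPARE was applied to Arabidopsis seedlings of 4 genotypes to locate processing intermediates of MIRNA precursors in wild-type and mutant plants. The genotypes were wild type (Col), fiery1, hyl1 and se, with 2 libraries each. HYL1 is a double-stranded RNA-binding partner of the nuclease DCL1, SE (SERRATE) is a zinc-finger protein of the same processing complex, and FIERY1 is a phosphatase whose loss inhibits the XRN exoribonucleases. The levels of the FIERY1, HYL1 and SE transcripts were not analysed here. Each tag starts at the 5′ end of a fragment that retained the 3′ part of a precursor, so its start marks a cleavage or degradation end. Values are relative within a library, because the primers enrich precursors and all tags share 1 total.

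Counts came from 108 precursors, and totals ranged from 35860 in a hyl1 library to 821562 in a fiery1 library. Over all tags MIR162a, whose miRNA targets DCL1, held the most counts in se, with 42.79% and 40.69% of the libraries, and in 1 wild-type library (24.04%) and 1 hyl1 library (15.37%). Nearly all of these were tags of 18 to 25 nt, 127463 of 128164 and 206804 of 207711 counts in se. In that wild-type library they were 18758 of 19269, and in that hyl1 library 5314 of 5513. MIR159b, whose miRNA targets MYB transcription factors, led the other wild-type library with 26.38% and 1 fiery1 library with 14.21%. MIR398b, whose miRNA targets copper/zinc superoxide dismutases, led the other fiery1 library with 16.25% and the other hyl1 library with 26.06%. Among tags of 26 nt or more MIR159b led both wild-type libraries, with 30.7% and 27.5% of their counts, and MIR169a, whose miRNA targets NF-YA transcription factors, led both se libraries, with 16.3% and 24.0%. Tags of 18 to 25 nt made up 86.1% and 83.9% of the counts in se, 29.5% and 4.05% in wild type, 3.70% and 3.23% in fiery1, and 1.19% and 28.2% in hyl1. Of these short-tag counts, 98.3% ended within 1 nt of 1 fixed base of their precursor, as did 71.15% of the counts of tags of 26 to 45 nt, 2.16% of 46 to 50 nt and 0.24% of 51 nt. No tag in the files was longer than 51 nt, so tags from longer fragments may end at that limit and could not reach the fixed base. The fall in these shares with length therefore does not show that long tags are another product. The tests of abundance, precision, lists and library measures are given over all tags and over tags of 26 nt or more. This division was chosen after the data were examined and does not set apart all tags that end at the fixed base. Values of single precursors are mostly given on 1 of these sets.

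The first comparison asked how processing intermediates differed between fiery1 and wild type. Ends at the base-proximal site held 66.5% ± 0.789 (SD, n = 2) of the counts in fiery1 and 37.1% ± 9.81 (SD, n = 2) in wild type. Ends at the loop-proximal site held 6.21% ± 0.653 in fiery1 and 24.4% ± 2.97 in wild type. Over tags of 26 nt or more, base-proximal ends were at 68.8% ± 1.07 against 44.4% ± 1.95, and loop-proximal ends at 6.42% ± 0.651 against 29.7% ± 3.01. The libraries of the genotypes did not overlap in any of these 4 measures, each with an exact permutation p of 0.333, the smallest that 2 libraries against 2 allow. For tags of 26 nt or more the base-proximal difference of 24.401 points was 15.747 without the 3 precursors with the most counts, 12.093 without MIR159b, 11.753 as a mean over precursors and 14.92 at the exact position, still without overlap.

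**Figure D1:**
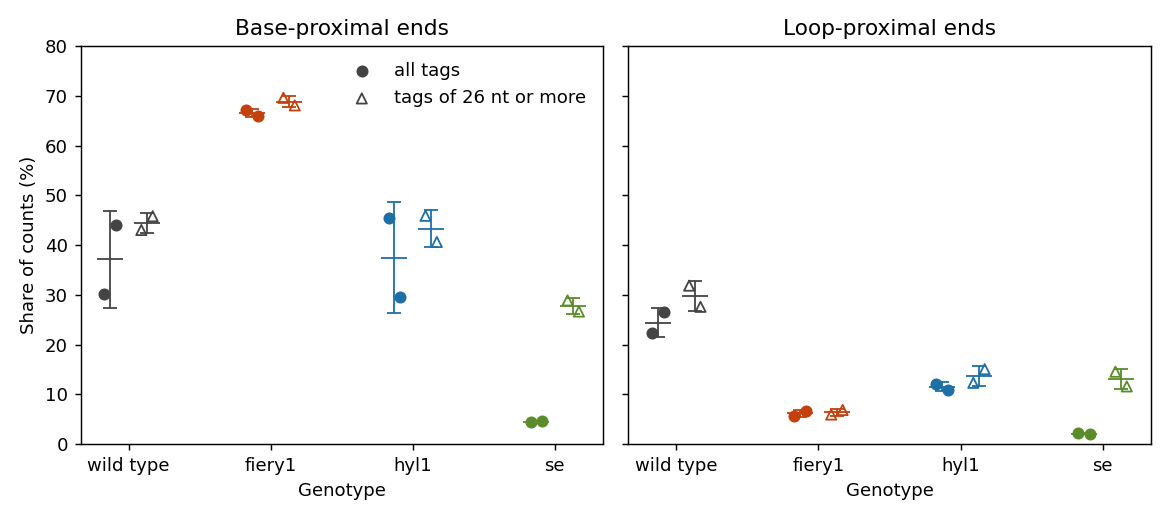
Share of counts (%, y axis) at base-proximal (left) and loop-proximal (right) ends by genotype, with filled circles for all tags, open triangles for tags of 26 nt or more, and bars for the mean ± SD of 2 libraries. fiery1 had the highest base-proximal share, 66.5% over all tags, and wild type had the highest loop-proximal share, 24.4%.

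Among 7 loop-to-base precursors with enough tags of 26 nt or more, 6 had a higher base-proximal share in both fiery1 libraries than in both wild-type libraries and 4 had a lower loop-proximal share. Of 16 other precursors 6 had a higher base-proximal share and 6 a lower one. MIR156a, whose miRNA targets SPL transcription factors, had 83.2% ± 3.78 base-proximal ends in fiery1 and 21.7% ± 0.02 in wild type, and its loop-proximal share was 6.08% ± 1.07 against 78.2% ± 0.05. MIR162a had 74.2% ± 0.01 against 27.8% ± 13.0 at the base and 3.68% ± 1.41 against 49.9% ± 6.11 at the loop. MIR171c, whose miRNA targets GRAS transcription factors, had 43.3% ± 13.9 against 0.06% ± 0.02 at the base. MIR159b (AT1G18075, TAIR10.1 chromosome 1, 6220646 to 6220841, plus strand) had 36.96% ± 1 against 5.46% ± 2.14 at the base and 18.8% ± 0.53 against 59.4% ± 0.42 at the loop. MIR171b overlapped between the genotypes, with base-proximal shares of 71.4% and 70.5% in fiery1 and 100% and 33.8% in wild type. MIR166a, of a base-to-loop family whose miRNA targets HD-ZIP transcription factors, had nearly all its ends at the base in both genotypes, 95.3% ± 0.18 in fiery1 and 100% in both wild-type libraries. These shares were described and not tested one by one.

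**Figure D2:**
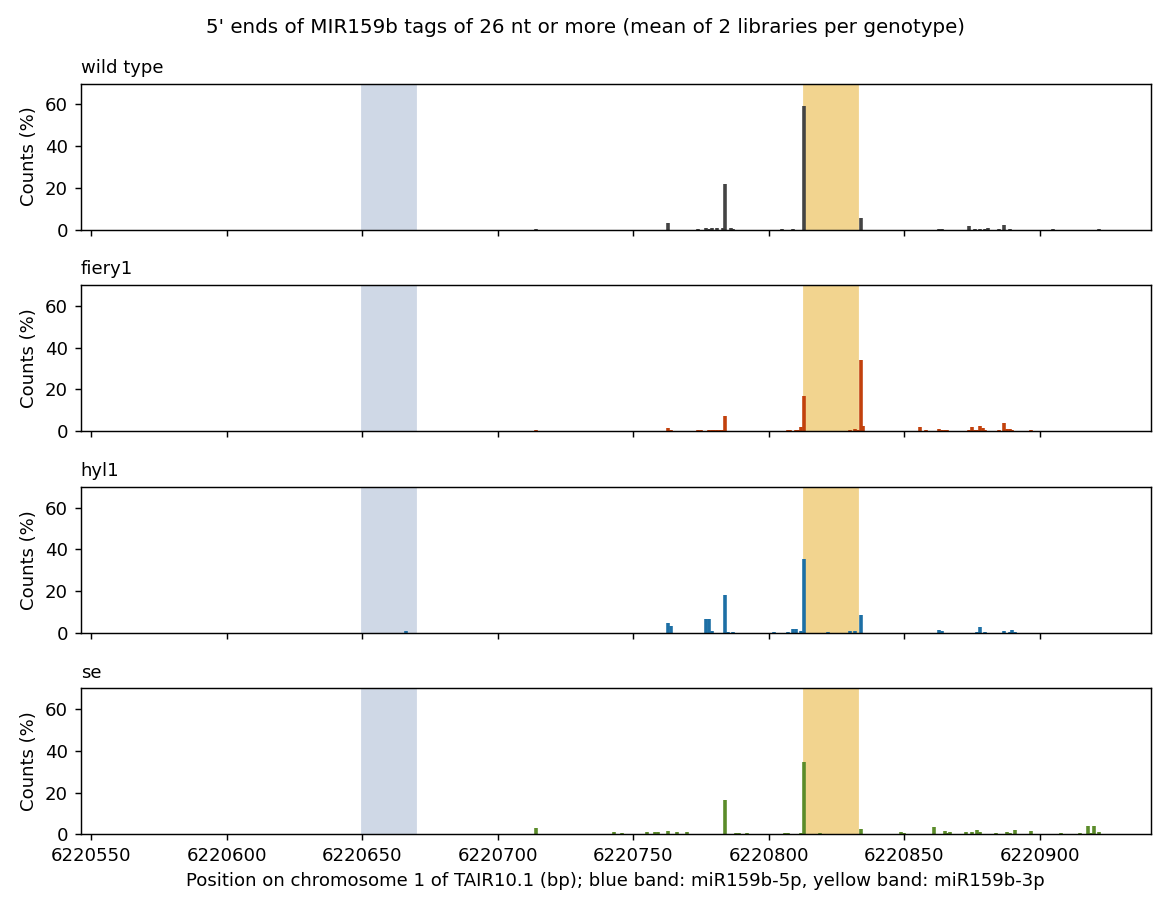
Share of MIR159b counts (%, y axis, mean of 2 libraries) starting at each base of chromosome 1 (x axis, bp) in tags of 26 nt or more, with a panel per genotype and bands for the miRNA strands of the duplex. The loop-proximal peak at the start of miR159b-3p (6220813 to 6220833) was the highest in wild type, hyl1 and se, whereas in fiery1 the highest peak lay just after its end.

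The share at the main position fell in MIR159b, from 59.4% ± 0.421 in wild type to 16.8% ± 0.766 in fiery1 (limma, adjusted p = 0.0394), among tags of 26 nt or more. It fell in MIR399b, whose miRNA targets the phosphate regulator PHO2, from 99.7% ± 0.360 to 59.6% ± 2.67 (adjusted p = 0.0259), and rose in MIR156c from 19.3% ± 20.5 to 91.2% ± 1.91 (adjusted p = 0.0456). The rise in MIR156c is that of 1 position (chromosome 4, 15415425), just after the end of miR156c-3p. Its 64542 counts over all libraries were of tags that match the reference exactly at 1 place and are listed for no other precursor. That position held 92.5% and 89.8% in the fiery1 libraries and at most 33.8% in any other library. Fiery1 thus carried its choice as main position, which favoured a rise in fiery1. These were the 3 of 18 precursors that passed, beside values of 3.94% ± 0.247 against 63.9% ± 20.2 in MIR156a and 2.51% ± 0.824 against 47.9% ± 12.6 in MIR171c. With a minimum of 10 counts MIR399b alone was called. Over all tags limma called 0 of 25, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0661. Leaving out the first or the second wild-type library left 3 and 4 calls among tags of 26 nt or more, and leaving out either fiery1 library left 0. Fiery1 also had more distinct positions at equal depth, 1005 ± 9.20 against 256 ± 39.5 in wild type, and 818 ± 4.15 against 145 ± 26.3 for tags of 26 nt or more (exact permutation p = 0.333 each). Median precision was 69.1% ± 1.22 against 74.7% ± 2.69 over all tags (exact permutation p = 0.333), and 72.2% ± 0.075 against 70.6% ± 6.94 for tags of 26 nt or more (exact permutation p = 1).

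In abundance, MIR164b (AT5G01747, chromosome 5, 287584 to 287736, plus strand), whose miRNA targets NAC transcription factors of the CUC type, rose in fiery1. It stood at 27575 ± 8861 normalised CPM against 91.8 ± 26.7 in wild type, a log2 fold change of 8.23 ± 1.70 (SE; edgeR, adjusted p = 0.0384), and was the only 1 of 101 precursors called over all tags. With DESeq2 size factors in edgeR it was not called, and the number called was 0. Among tags of 26 nt or more, 10 of 74 precursors rose and 5 fell. Of those that rose, 7 had no count in either wild-type library. The sulfate-responsive MIR395c was at least 13.5-fold higher and MIR395f at least 10.06-fold higher, both encoding miRNAs that target ATP sulfurylases and a sulfate transporter. MIR397a, whose miRNA targets laccases, was at least 9.79-fold higher, and MIR171a at least 6.01-fold, MIR771 at least 5.82-fold, MIR447a at least 4.28-fold and MIR162b at least 3.45-fold higher. These folds are the fiery1 mean over the wild-type floor of 42.4 CPM, which covers counting error only. Whole precursors could be missing from 1 wild-type library, as MIR824 was with 0 and 939 counts and MIR165b with 0 and 343. MIR395f, MIR171a, MIR771, MIR447a and MIR162b had no such tags in hyl1 or se either, so they passed the filter through fiery1 alone. MIR771 stood at 373 and 120 CPM in the fiery1 libraries. Over all tags MIR397a had a log2 fold change of -1.19, with 228 wild-type counts, and MIR395c one of 1.55, with 44. Those wild-type counts were all short tags. The others of the 7 had positive values over all tags, and none of the 7 was called there. Among tags of 26 nt or more MIR164b rose by 7.97 ± 1.98 (SE) on the log2 scale, and MIR156c by 3.11 ± 0.71 through that 1 position. MIR168b, whose miRNA targets AGO1, rose to 46.2 times the wild-type level (95% counting interval 8.25 to 1828, from 1 wild-type count). The precursors that fell were MIR166b with a log2 fold change of -4.25 ± 1.07 (SE), MIR399a with -3.81 ± 0.83, MIR171c with -2.50 ± 0.70, MIR157c with -2.44 ± 0.52 and MIR159b with -1.75 ± 0.40. The adjusted p of these 15 calls by edgeR lay between 0.0181 and 0.0362.

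By list, 2 of the 4 sulfate precursors rose among tags of 26 nt or more, and 4 when adjusted over the list alone. MIR395a had 5001 counts in fiery1 and 6 in wild type (log2 fold change 6.40, adjusted p = 0.0780), and MIR395b had 5269 and 4. Camera called the sulfate list as higher (adjusted p = 0.0133), the only 1 of 11 lists, and the call was lost at an adjusted p = 0.295 with an estimated correlation. Without the first wild-type library 0 lists were called, without the second 2, and without either fiery1 library 1. The phosphate list had 1 of 4 members lower, 2 adjusted over the list alone (camera adjusted p = 0.0685). Loop-to-base families had 3 of 17 members higher and 2 lower (6 and 2 adjusted over the list alone), and the sequential families 1 of 5 lower (1 over the list alone). Base-to-loop families had 5 of 38 higher and 2 lower (5 and 2 over the list alone), development regulators 3 of 42 in each direction (3 and 2), and nutrient-responsive families 3 of 12 higher and 1 lower (5 and 2). Silencing-pathway regulators had 2 of 5 higher, copper families 1 of 4 and families outside the conserved numbers 2 of 10, with the same counts adjusted over each list alone, and auxin-receptor and ARF families had 0 of 9 by both.

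**Figure D3:**
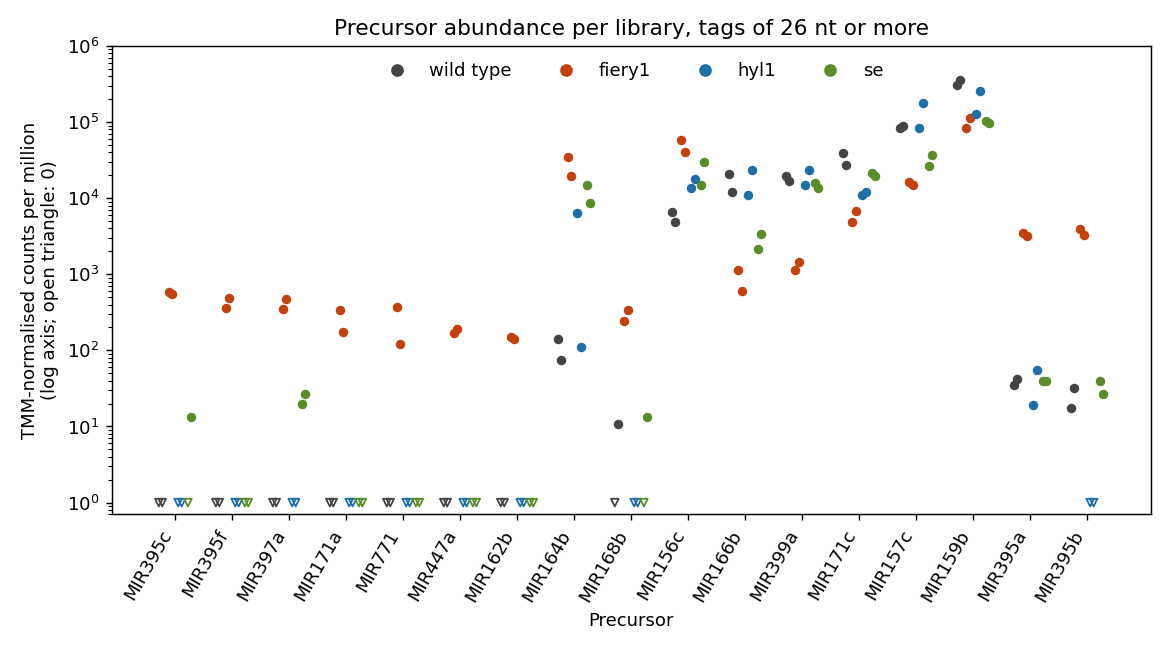
TMM-normalised CPM (y axis, log scale) of precursors called between fiery1 and wild type in tags of 26 nt or more, plus MIR395a and MIR395b, with a point per library, colours for the 4 genotypes and open triangles for libraries without counts. The first 7 precursors had no tags of 26 nt or more in either wild-type library and had such tags in both fiery1 libraries.

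Over all tags the sulfate list had 0 of 5 members called, by both adjustments, and camera called 0 of 11 lists, or 1 without the second wild-type library. The calls adjusted over a list alone were 1 higher in each of the loop-to-base and base-to-loop families, 2 higher among development regulators, 3 higher and 1 lower among silencing-pathway regulators, 1 lower in the phosphate list, and 0 in the others. Counts at an unadjusted p under 0.05 were 30 over all tags and 27 over tags of 26 nt or more, and DESeq2 called 20 and 18. The libraries of the genotypes did not overlap for 61.4% and 73.0% of precursors, where chance gives 33.3% for libraries that are alike in depth. Depth differed between the genotypes, so a precursor near 0 in shallow libraries could stand apart through depth alone. The excess over 33.3%, here and below, was not tested. The median log2 fold change over tags of 26 nt or more was 1.34, or 1.91 on library totals. With a term for libraries with later sample numbers 15 precursors were called over all tags. Limits were that leaving out any 1 of the 4 libraries left 0 calls over all tags, and among tags of 26 nt or more 0 without the first wild-type library, 2 without the second and 0 without either fiery1 library. With a replicate block 0 calls remained among tags of 26 nt or more, with the most used position of each precursor left out 1 remained, and MIR156c then had a log2 fold change of -0.10, and -1.87 over all tags with 0 in the hits column, whose meaning is not stated and which was 1 for each tag at that position.

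The second comparison asked what the loss of HYL1 changed. Loop-proximal ends held 11.6% ± 0.868 (SD, n = 2) of the counts in hyl1 and 24.4% ± 2.97 (SD, n = 2) in wild type, and 13.7% ± 1.94 against 29.7% ± 3.01 for tags of 26 nt or more (exact permutation p = 0.333 each). Part of this difference went with MIR159b. Among tags of 26 nt or more it held 14.7% and 17.6% of the counts in hyl1 and 30.7% and 27.5% in wild type. Its main position, at the loop, held 35.3% of its counts in hyl1 and 59.4% in wild type. Base-proximal ends held 37.5% ± 11.2 against 37.1% ± 9.81, and 43.3% ± 3.72 against 44.4% ± 1.95 (exact permutation p = 1 each), values that depended on the precursors counted. Without the 3 precursors with the most counts the difference was -13.928 points, and -11.806 for tags of 26 nt or more, with no overlap (exact permutation p = 0.333 each). Without MIR159b it was -5.678 and -11.207 points, and as a mean over precursors -0.415 and -11.688. The share of a precursor's ends at its main position was also lower. That position is shared by the 4 genotypes. A move of ends to another position therefore lowers the share too, even if they stay concentrated. Median precision was 57.0% ± 1.88 in hyl1 and 74.7% ± 2.69 in wild type, and 52.0% ± 0.985 against 70.6% ± 6.94 for tags of 26 nt or more (exact permutation p = 0.333 each). Distinct positions at equal depth numbered 294 ± 11.9 against 256 ± 39.5, and 197 ± 23.7 against 145 ± 26.3 (exact permutation p = 0.333 each).

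The share at the main position of MIR399b fell in hyl1, from 99.7% ± 0.360 to 68.8% ± 20.4, the only 1 of 18 precursors called over tags of 26 nt or more (limma, adjusted p = 0.0408). The number called was 0 with the replicate block, with only the 2 genotypes in the model and with the inverse Simpson index. Values that did not pass included MIR159b at 35.3% ± 3.79 against 59.4% ± 0.421, MIR171c at 9.99% ± 12.8 against 47.9% ± 12.6 and MIR162a at 1.16% ± 0.930 against 27.7% ± 12.9. MIR779 stood at 31.1% ± 15.3 against 70.9% ± 2.63. Among these, MIR171c and MIR162a alone changed sign on the inverse Simpson index, which fixes no position. Their ends were then more concentrated in hyl1, by 0.13 and 0.41 on its negative log. The main position of MIR162a had its highest shares in fiery1, 72.8% and 71.8%. Over all tags limma called 0 of 25, with 2 at an unadjusted p under 0.05. Without the first or second wild-type library 2 and 1 precursors were called over tags of 26 nt or more, and without the first or second hyl1 library 2 and 0. MIR156a kept most of its ends at the loop, 77.0% ± 2.33 in hyl1 and 78.2% ± 0.05 in wild type, with 0.16% ± 0.03 against 21.7% ± 0.02 at the base.

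No precursor passed in abundance between hyl1 and wild type. edgeR called 0 of 101 over all tags, with 22 at an unadjusted p under 0.05, a smallest adjusted p of 0.154 and 18 called by DESeq2. Over tags of 26 nt or more it called 0 of 74, with 14 at an unadjusted p under 0.05, a smallest adjusted p of 0.225 and 20 called by DESeq2. The smallest p-values over all tags belonged to MIR164b, with a log2 fold change of 5.80 ± 1.54 (SE), and to MIR157a, at 481 times the wild-type level (95% counting interval 85.4 to 19106), with 10 and 189 counts in the hyl1 libraries. MIR156c had a log2 fold change of 1.94, MIR165a of -2.31 and MIR169l/MIR169k of -5.24, and MIR156d, without counts in hyl1, was at least 26.6-fold lower. Among tags of 26 nt or more the smallest p-values belonged to MIR157a, MIR164b (4.93), MIR167c, MIR169l/MIR169k (-6.47), MIR160a (6.73) and MIR165a (-2.12). Of these, 3 rested mainly on 1 hyl1 library, with 9 and 189 counts for MIR157a, 334 and 2 for MIR164b, and 36 and 0 for MIR167c. Over all tags the value of MIR169l/MIR169k was 0.27 without the second wild-type library.

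None of the 11 lists was called by camera, and each list had 0 members called by edgeR, over all precursors and adjusted over the list alone. The libraries of hyl1 and wild type did not overlap for 27.7% of precursors over all tags and 32.4% over tags of 26 nt or more, beside 33.3% by chance. Leaving out either hyl1 library, or a term for later sample numbers, gave 1 call over all tags, and leaving out the first wild-type library gave 2 over tags of 26 nt or more. The hyl1 libraries had the fewest counts, and by counting error alone a precursor without counts there could stand anywhere under the floor of 82.3 CPM. It could also stand above that floor. Among tags of 26 nt or more, 43 of 85 positions with 100 counts or more in the first hyl1 library were absent from the second. The fold given for MIR156d is therefore not a strict bound.

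The third comparison asked what the loss of SE changed. Over all tags 7 precursors rose and 10 fell in se among 101 tested. Those that fell included precursors abundant in wild type. MIR159b stood at 18476 ± 1450 normalised CPM against 280540 ± 95001 (SD, n = 2 each), a log2 fold change of -3.92 ± 0.55 (SE; edgeR, adjusted p = 0.00104). MIR166a and MIR166b had log2 fold changes of -4.97 ± 1.23 and -4.29 ± 1.21, and MIR165a, of the same HD-ZIP-targeting group, -3.82 ± 0.89. The phosphate-responsive MIR399c had -3.88 ± 0.79, and the copper-responsive MIR408 and MIR398b had -3.18 ± 0.72 and -2.46 ± 0.69. MIR825 had -5.10 ± 1.57, MIR157c -4.00 ± 0.68 and MIR779 -2.35 ± 0.70, and the adjusted p of the 17 calls was at most 0.0435.

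The precursors that rose in se over all tags were seen mainly as short tags, apart from MIR391 in 1 se library. MIR156e, whose miRNA targets SPL transcription factors, had 77592 counts in se and 193 in wild type, a log2 fold change of 6.24 ± 1.02 (adjusted p = 0.00225), but 0 counts in tags of 26 nt or more in both genotypes. MIR156c had a log2 fold change of 2.71, and MIR157a was at 657 times the wild-type level (95% counting interval 118 to 25951, from 1 wild-type count). MIR162b was at least 8.08-fold, MIR5023 at least 7.69-fold, MIR391 at least 7.02-fold and MIR5648 at least 4.50-fold higher. Over tags of 26 nt or more edgeR called 0 of 74 precursors, with 16 at an unadjusted p under 0.05, a smallest adjusted p of 0.213 and 21 called by DESeq2. The smallest p-values there belonged to MIR159b with a log2 fold change of -1.71, MIR164b with 6.76, MIR156c with 1.98 and MIR157c with -1.43. MIR160c was at 470 times the wild-type level (95% counting interval 130 to 3891), and MIR827, without counts of such tags in se, had 71 and 1 in the wild-type libraries. As short tags MIR827 had 59 and 313 counts in se. MIR779 had 0.23 there, on the other side of 0 from its value over all tags. The other precursors that fell over all tags had smaller values there, -3.20 for MIR166a, -2.57 for MIR166b, -1.29 for MIR165a, -1.37 for MIR399c, -0.64 for MIR408, -0.41 for MIR398b and -3.09 for MIR825, none of them called.

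Camera called 0 of 11 lists in se against wild type on either set of tags. By edgeR over all tags, 6 of 53 base-to-loop precursors fell and 0 rose, 3 of 21 loop-to-base precursors rose and 1 fell, and 1 of 5 sequential loop-to-base precursors fell. Copper families had 2 of 5 lower, the phosphate list 1 of 6 lower, nutrient-responsive families 3 of 16 lower, development regulators 2 of 57 higher and 4 lower, and silencing-pathway regulators 1 of 5 higher. The same counts were found adjusted over each list alone. Families outside the conserved numbers had 2 of 16 higher and 2 lower (3 and 2 adjusted over the list alone), and the sulfate and the auxin-receptor and ARF lists had 0 of 5 and 0 of 9 by both. Each list had 0 calls over tags of 26 nt or more, and adjusted over the list alone the loop-to-base and sequential lists had 1 lower each.

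Over all tags, base-proximal ends held 4.54% ± 0.217 of the counts in se against 37.1% ± 9.81 in wild type, and loop-proximal ends 2.14% ± 0.133 against 24.4% ± 2.97. The shares over tags of 26 nt or more were 27.8% ± 1.58 against 44.4% ± 1.95 and 13.1% ± 2.10 against 29.7% ± 3.01. Median precision was 45.2% ± 4.69 against 74.7% ± 2.69, and 32.6% ± 2.32 against 70.6% ± 6.94 over tags of 26 nt or more. Distinct positions at equal depth numbered 412 ± 20.4 against 256 ± 39.5, and 270 ± 37.5 against 145 ± 26.3. The exact permutation p was 0.333 for each of these 8 comparisons, with no overlap between the genotypes. In single precursors of tags of 26 nt or more, the main position of MIR169a held 28.3% ± 1.21 in se against 89.5% ± 2.72, or 59.68% ± 1.46 against 97.12% ± 2.27 without its tags of 26 to 45 nt, and that of MIR166b 0.849% ± 0.074 against 90.1% ± 13.955. In the second se library all 251 counts of MIR166b still lay within 1 nt of the base-proximal site, against 0.90% of 111 in the first. limma called 0 of 18 precursors there and 0 of 25 over all tags, with 2 and 10 at an unadjusted p under 0.05.

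Without the first or second wild-type library 8 and 3 of the 17 calls between se and wild type over all tags were made again, as were 4 without the first se library, while 16 were made without the second, 13 of them shared. With the most used position left out 5 were called, and MIR166a and MIR399c had log2 fold changes of 8.80 and 1.11. With DESeq2 size factors 10 precursors were called, with a term for later sample numbers 28 were, DESeq2 itself called 41, and the median log2 fold change over all tags was 1.61 with TMM, 1.13 with DESeq2 size factors and 1.88 on library totals. Counts at an unadjusted p under 0.05 numbered 37, and the libraries did not overlap for 66.3% of precursors, or 45.9% over tags of 26 nt or more, beside 33.3% by chance. For limma, leaving out the second wild-type or second se library gave 1 and 2 calls over all tags, and over tags of 26 nt or more leaving out the second wild-type library gave 2 and any other library 1. edgeR called 1 precursor over tags of 26 nt or more without the first wild-type library.

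The fourth comparison set se against hyl1, the mutants of both processing partners of DCL1. Over all tags MIR156e rose in se, with a log2 fold change of 5.37 ± 0.98 (edgeR, adjusted p = 0.00334), and 7 precursors fell. MIR157c had a log2 fold change of -4.55 ± 0.70 (adjusted p = 0.00257), MIR166a of -4.64, MIR399c of -4.44, MIR166b of -4.38, MIR408 of -3.75, MIR159b of -3.07 and MIR398b of -2.96. Over tags of 26 nt or more edgeR called 0 of 74, with 16 at an unadjusted p under 0.05, a smallest adjusted p of 0.147 and 15 called by DESeq2. The smallest p-values there belonged to MIR827, without counts in se and at least 407-fold lower, MIR157c (-2.04), MIR160c (at least 51.9-fold higher), MIR169l/MIR169k (8.44), MIR169a (2.90) and MIR156b, with 17 and 0 counts in the hyl1 libraries and none in se. Over all tags MIR827 had 59 and 313 counts in se and a log2 fold change of -5.31, and MIR160c had 1 and 19 counts in hyl1. The precursors called over all tags had values there of -3.11 for MIR166a, -2.64 for MIR166b, -1.76 for MIR399c, -1.44 for MIR408, -0.91 for MIR159b and -0.79 for MIR398b. Short tags made up 86.1% and 83.9% of the counts in se and 1.19% and 28.2% in hyl1. Falls over all tags could follow from that here too.

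The share of counts at the main position of MIR166b fell from 98.8% ± 1.63 in hyl1 to 0.629% ± 0.363 in se over all tags (limma, adjusted p = 0.0399). It rose in MIR779 from 30.97% ± 15.2 to 84.1% ± 2.81 and in MIR160a, whose miRNA targets auxin response factors, from 5.54% ± 6.38 to 69.8% ± 20.6 (adjusted p = 0.0399 each). Of the MIR160a counts, 843 of 1142 and 1444 of 1449 in the se libraries were short tags, against 3 of 292 and 27 of 179 in hyl1. MIR160a had too few tags of 26 nt or more to be tested on them. Over tags of 26 nt or more MIR399b rose from 68.8% ± 20.4 to 99.8% ± 0.158, MIR779 rose and MIR166b fell, the 3 of 18 precursors called (adjusted p = 0.0148, 0.0235 and 0.0148). For MIR166b this was a shift of 1 nt in the second se library, where 100% of those tags stayed within 1 nt of the base-proximal site. Over all tags 0 precursors were called with 1 nt on each side of the main position, with only the 2 genotypes in the model, with a minimum of 10 counts or with a term for later sample numbers, and 1 with the replicate block. Base-proximal ends held 4.54% ± 0.217 in se and 37.5% ± 11.2 in hyl1, or 27.8% ± 1.58 and 43.3% ± 3.72 over tags of 26 nt or more (exact permutation p = 0.333 each). Loop-proximal ends held 2.14% ± 0.133 against 11.6% ± 0.868 (exact permutation p = 0.333), but 13.1% ± 2.10 against 13.7% ± 1.94 over tags of 26 nt or more (exact permutation p = 0.667). Median precision was 45.2% ± 4.69 against 57.0% ± 1.88, and 32.6% ± 2.32 against 52.0% ± 0.985 (exact permutation p = 0.333 each). Distinct positions at equal depth were at 412 ± 20.4 against 294 ± 11.9, and 270 ± 37.5 against 197 ± 23.7 (exact permutation p = 0.333 each). Without the first hyl1 library or either se library limma called 0 precursors over all tags, and 6 without the second hyl1 library. It called, over tags of 26 nt or more, 3 and 2 without the first and second hyl1 library, and 4 and 6 without the first and second se library.

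Camera called 0 of 11 lists between se and hyl1 on either set of tags. Over all tags edgeR called 5 of 53 base-to-loop precursors lower (5 adjusted over the list alone), 1 of 21 loop-to-base precursors higher and 1 lower (1 and 2), 1 of 5 sequential precursors lower (1), and 1 of 57 development regulators higher and 3 lower (1 and 2). Nutrient-responsive families had 3 of 16 lower (1 higher and 6 lower adjusted over the list alone), copper families 2 of 5 lower (1 higher and 3 lower), and the phosphate list 1 of 6 lower (3). The sulfate, silencing-pathway, auxin and outside lists had 0 by both. With tags of 26 nt or more each list had 0 calls, and adjusted over the list alone the phosphate list had 2 lower and the nutrient-responsive families 1 lower.

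Of the 8 calls between se and hyl1, with 30 precursors at an unadjusted p under 0.05 and 32 called by DESeq2, 0 were made when the model held only these 2 genotypes, and MIR166b had a log2 fold change of 2.79 with its most used position left out. Without the first or second hyl1 library 12 and 19 precursors were called, and without the first or second se library 5 and 7. Leaving out either hyl1 library gave 1 call over tags of 26 nt or more. The libraries did not overlap for 61.4% of precursors over all tags and 43.2% over tags of 26 nt or more, beside 33.3% by chance, and the median log2 fold change was 0.73, or 0.37 with DESeq2 size factors. The 3 mutants were compared with the same wild-type libraries, and overlaps between those comparisons were not tested.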

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

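Of the results that answer a comparison, 456 values stayed on the same side under an alternative, 74 were stronger, 45 weaker and 19 reversed, and of the single precursors 1246, 125, 306 and 16. The cause was not tested for any of the values below. Where a library was left out, the lone library was assumed to vary like the other groups. Below, tags of 26 nt or more are called long tags. Counts are of calls, in the order fiery1, hyl1, se (each against wild type) and se against hyl1 where all are given.

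Abundance calls with the DESeq2 Wald test were 20, 18, 41 and 32, and for long tags 20 in hyl1, 21 in se and 15 in se against hyl1. DESeq2 size factors gave 0 in fiery1, 10 in se and, for long tags, 1 in se against hyl1. Library totals gave 2 in fiery1. No filter gave 6 in fiery1, and for long tags 5 in fiery1, 2 in se and 2 in se against hyl1. The stricter filter gave 2 in se and 1 in se against hyl1 for long tags. With only the 2 groups compared there were 23 in fiery1, 28 in se and 0 in se against hyl1, and for long tags 40 in fiery1 and 1 in se. Thinned to the shallowest library there were 6 in fiery1 and 13 in se against hyl1, and for long tags 2 in se and 2 in se against hyl1. Long tags gave 15 in fiery1, 0 in se and 0 in se against hyl1, with MIR779 at 0.23 in se. Tags of 31 nt or more gave 15, 2 in se and 1 in se against hyl1, and tags of 46 nt or more 14, 2 and 1. File entries kept apart gave 10 in se, and tags with 0 in the hits column, whose meaning is not stated, put MIR156c at -1.87 in fiery1. With the most used position left out there were 2 calls in fiery1 (1 for long tags) and 5 in se. MIR156c was then at -0.38 in fiery1 (-0.10 for long tags), MIR166a at 8.80 and MIR399c at 1.11 in se, and MIR166b at 2.79 in se against hyl1.

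The replicate block gave 2 abundance calls in fiery1, 11 in se and 0 for long tags in fiery1, 1 precision call in se against hyl1, 0 for long tags in hyl1, and 2 lists for long tags in fiery1. The correlation of replicate differences lay between -0.139 and 0.1 for the pairs of groups compared. The crossed block, which set the first library of se or hyl1 with the second of wild type, gave 12 calls in se (3 higher and 9 lower) and 0 for long tags in hyl1.

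The first hyl1 and the second se library carry later sample numbers than the other 6, and may have been prepared apart. A term for them, chosen after the results were seen, gave 15 abundance calls in fiery1, 1 in hyl1 and 28 in se, and 1 precision call in fiery1, 1 in se and 0 in se against hyl1, and moved no other count by over 1.5 times. Within the earlier libraries, with 1 of hyl1 and 1 of se, the loop-proximal share was 10.97% in hyl1, 2.234% in se and 24.44% in wild type, and the median precision 58.293%, 41.921% and 74.673%. The base-proximal share of se minus hyl1 was -25.173 in the earlier and -40.672 in the later libraries, and -11.73 and -19.226 for long tags. Wild type and fiery1 had no library with a later number.

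Precision calls with only the 2 groups compared were 7 in fiery1 and 0 in se against hyl1, and for long tags 9 in fiery1, 0 in hyl1 and 1 in se against hyl1. Long tags gave 3 in fiery1 and 1 in hyl1. The inverse Simpson index gave 3 in fiery1 and 8 in se, and for long tags 0 in hyl1 and 6 in se. It put MIR156a at 0.20 and MIR160a at 0.72 in fiery1, MIR160a at 0.24 in hyl1 and MIR156c at 0.86 in se. For long tags it put MIR156a at 0.20 in fiery1, MIR171c at 0.13 and MIR162a at 0.41 in hyl1, and MIR166b at 0.18 in se. These are differences of its negative log. Positive values mean more concentrated ends, whereas the share at the main position was lower in each of these cases. With 1 nt on each side there were 5 in fiery1, 1 in hyl1, 8 in se and 0 in se against hyl1, and the median precision of long tags differed by -1.20 in fiery1. A minimum of 10 counts gave 0 in se against hyl1 and 1 for long tags in fiery1, and a minimum of 50 counts 2 in fiery1 and 8 in se. Lists called were 1 for long tags in fiery1 with camera and 0 with the estimated correlation. With fry they were 2 in fiery1, 2 in se and 4 in se against hyl1, and for long tags 10 in fiery1 and 3 in se against hyl1.

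The base-proximal share of hyl1 minus wild type was -1.159 for long tags, -0.415 as a mean over precursors, -5.678 without MIR159b and -13.928 without the 3 precursors with the most counts, and for long tags 1.001 at the exact position and 0.142 in a window of 2 nt. The loop-proximal share of se minus hyl1 for long tags was 2.462 as a mean over precursors, 0.895 without MIR159b and 4.41 without the 3 precursors with the most counts. Median precision differed by 1.60 in fiery1 for long tags, and distinct positions by -35.5 in hyl1 when not thinned.

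With each library left out in turn, abundance calls ranged from 0 to 0 in fiery1, 0 to 1 in hyl1, 3 to 16 in se and 5 to 19 in se against hyl1, and for long tags from 0 to 2, 0 to 2, 0 to 1 and 0 to 1. MIR169l/MIR169k ranged from -6.22 to 0.27 in hyl1. Precision calls ranged from 0 to 2 in se and 0 to 6 in se against hyl1, and for long tags from 0 to 4, 0 to 2, 1 to 2 and 2 to 6. Lists ranged from 0 to 1 in fiery1 and 0 to 2 for long tags. The base-proximal share of hyl1 minus wild type ranged from -7.55 to 8.26, and from -3.79 to 1.47 for long tags. For long tags the loop-proximal share of se minus hyl1 ranged from -2.10 to 0.868 and the median precision of fiery1 minus wild type from -3.31 to 6.51. Depth set the floor for a precursor without counts, 82.3 CPM in hyl1 and 34.1 CPM in wild type over all tags.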

Other observations

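The predictions on primer products and on cleavage near the primer were written before their tests were run, after the short tags had been seen. The tests on the base-proximal and loop-proximal ends of fiery1, on its number of positions and on the gap between replicate libraries in short tags were chosen only after the results were seen. Outside the base-proximal and loop-proximal sites, tags of 26 nt or more also differed between genotypes in where they started, by values that were not tested. Ends downstream of the base-proximal site held 28.4% and 29.4% of the counts in the se libraries, 10.6% and 5.68% in wild type, 9.55% and 11.1% in fiery1 and 6.44% and 13.4% in hyl1. Ends upstream of the duplex strand on the 3′ arm held 24.3% and 20.1% in hyl1, 15.9% and 16.9% in se, 9.33% and 13.7% in wild type and 5.47% and 5.62% in fiery1. Ends within the duplex strand on the 3′ arm held 12.2% and 15.5% in se, 11.1% and 10.8% in hyl1, 9.45% and 8.32% in fiery1 and 5.22% and 7.19% in wild type.

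Among families over tags of 26 nt or more, 6 of 7 MIR169 precursors, whose miRNAs target NF-YA transcription factors, had positive log2 fold changes in se against wild type, with libraries apart for 5 and 0 called. In fiery1 against wild type, all 4 MIR167 precursors, whose miRNAs target auxin response factors, had positive values with libraries apart and 0 called. Of all 74 precursors tested there, 39 were higher with libraries apart, and the median was 1.34. MIR167b lay below that median at 0.83, and MIR167a, MIR167c and MIR167d above it at 1.65, 8.69 and 5.62. The 3 MIR399 precursors had negative values, 1 of which was positive on library totals. The MIR166 family had 1 of 3 members called lower in fiery1, and its 3 members had negative values in se against wild type with 0 called. MIR156 had 1 of 4 members called higher in fiery1. MIR172 was described over all tags alone, where its 4 precursors had positive values in se against wild type with TMM, 3 of them with DESeq2 size factors, and 0 called.

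Short tags made up most of the se libraries. A candidate explanation is products of the precursor-specific primers without an insert, and 90.9% of the short-tag counts of se started within 1 nt of the start most used in the other libraries, as did 95.9% in wild type, 92.6% in fiery1 and 87.5% in hyl1. Cleavage close to the primer that is more frequent in se also met its prediction, since tags of 26 to 45 nt held 12.52 points more of the counts in se than in wild type. That prediction was met through MIR169a alone, which made up 80.4% of the se counts of that length, and without it the shares were 4.18% and 3.14% in se and 0.224% and 0.096% in wild type, a difference of 3.5 points where 10 had been predicted, so it stays open for the other precursors. Genotype and library preparation cannot be told apart here, because the share also differed by 27.0 points between the hyl1 libraries and by 25.4 points between the wild-type libraries.

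The higher base-proximal and lower loop-proximal shares in fiery1 were not accounted for in full by which precursors were counted, though part of the difference went with them. Over tags of 26 nt or more the base-proximal difference of 24.401 points was 16.8 averaged over the same 23 precursors, with a loop-proximal difference of -15.8 points, and 15.747 without the 3 most counted precursors. Slower removal of the 3′ fragments, since FIERY1 loss inhibits the XRN exoribonucleases, or a change of processing may be behind it, as a hypothesis. In 6 of 7 loop-to-base precursors the base-proximal share was higher in both fiery1 libraries, with the loop-proximal share lower in 4, while of 16 other precursors 6 were higher and 6 lower. Stability, processing and library preparation cannot be told apart, with 2 libraries per genotype.

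Fiery1 libraries held more distinct positions than the others. Sequencing depth is unlikely to be the cause, since at equal depth fiery1 still had 5.64 times the positions of wild type in tags of 26 nt or more and 3.93 times over all tags. A low number of starting molecules in the other libraries may contribute, because among positions with 100 counts or more at least 21.9% and up to 50.6% were absent from the second library of the same genotype in wild type, hyl1 and se, against 0.0% in fiery1. Sequencing of 1 amplified pool as both fiery1 libraries, with no further PCR, is argued against by tag counts that differed more than by sampling, with a chi-square over its degrees of freedom of 55.8, beside 229.5 in wild type, 132.9 in hyl1 and 158.1 in se. Such values grow with the number of counts, which was largest in fiery1, so they do not rank the genotypes. The fiery1 libraries had the lowest value despite that. Sharing of cDNA before the last PCR stays open, as does a biological difference in fiery1 plants, which was not tested.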
